A study of Homo sapiens with 9 samples.

How the data were processed

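Human umbilical artery endothelial cells in 3 groups of 3 libraries were measured by mRNA sequencing: scramble siRNA in growth medium (control), scramble siRNA in EndMT-induction medium with TGFβ2 (TGFβ), and ACSS2 siRNA in induction medium (siACSS2). Groups were taken from the labels, which number the replicates 1 to 3. Libraries were made with a SMARTer kit, per the labels' protocols, and the submitters' processing notes name STAR for alignment and edgeR, without versions. The second deposited table holds expected counts, that is estimated counts of reads per transcript model, for 84177 models. The first deposited table holds RPM, reads per transcript model scaled to library size, with a small constant added to each and no correction for length, for 44321 models. Both units were read from the values, since the deposited files do not state how they were made. Every expected count model in the deposited table has a sum of at least 10 over the libraries.

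For each gene, estimated counts of its models were summed and rounded, which gave 20465 symbols, and RPM values were summed to 16293 symbols. Of the symbols, 1152 and 403 older ones were replaced by current ones, and 24 genes whose symbols had been turned into dates by a spreadsheet were kept without a name. Sex-linked marker genes were left out of every table. The design, fixed before any value was seen, expected limma on log2 values and edgeR if a table held counts. As the second table holds estimated counts, the edgeR quasi-likelihood test (glmQLFit, glmQLFTest) was used, with TMM factors and 1 fit of all 9 libraries by group. CPM values printed were computed here from the deposited expected counts and scaled by TMM factors. Genes at 1 CPM or more in at least 3 libraries were tested (13850), with a Benjamini-Hochberg adjusted p under 0.05. PECAM1 is present only in the deposited RPM table, where limma was run on log2(value + 1) of 12791 genes.

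Libraries held 27735299 to 34929323 estimated counts. TMM factors were 0.994 to 1.01 in control, 0.910 to 0.919 in TGFβ and 1.09 to 1.10 in siACSS2 libraries, and edgeR's common coefficient of variation was 0.0640. Where a group held 3 or fewer counts, a ratio with a 95% counting interval is given, or, for 0 counts, a bound against 3 counts over the group. On simulated data drawn from the real means and library sizes, edgeR made 13, 16 and 19 false calls among 13614 unchanged genes in the 3 comparisons, and camera found the changed list and 0 of the others. Simulated genes were drawn independently of one another and few were changed. The simulation therefore does not test camera under correlation between genes, or TMM factors when many genes change. Each p-value is two-sided.

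Before any value was seen, 29 gene lists were fixed, of which 28 had 3 or more tested members and 1, epithelial markers, did not. They cover TGFβ targets, pathway components, BMP targets, mesenchymal genes, matrix, EMT factors, endothelial, arterial and venous identity, FGF and VEGF signalling, acetate, glycolysis, TCA, cholesterol and fatty acid metabolism, inflammation, interferon, cell cycle, stress, hypoxia, acetyltransferases, other cell types and RNA quality. Lists were tested with camera (limma) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and beside it with an estimated correlation and with fry. Genes named in the text are ACSS2, the 10 largest rises and falls with a mean of at least 5 CPM and no overlap between the 2 groups, the 3 list members with the smallest adjusted p, a fixed panel, and the 10 strongest opposite changes. List members outside that rule that are named because 5 or fewer moved one way, and the other list members, THBS1 and the genes shown in the plot of single libraries, and RND1 in the closing section, were chosen after their values were seen. COL1A1, SNAI2 and TWIST1 of the panel are not analysed here.

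Alternatives were no filter, a minimum of 5 CPM, DESeq2 size factors, upper quartile factors, library totals alone, the DESeq2 test, limma-voom, only the 6 libraries compared, a replicate block, each library left out and, for RPM values, pseudocounts, filters, scaling and the variance trend. The RPM table in place of the counts was added after seeing the data. Exact splits of 3 against 3 libraries number 10. Gene types and 3' UTR sequences came from GENCODE 29 and were used only for tests in the closing section. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.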

Results

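Primary human umbilical artery endothelial cells, the cells that line the arteries of the umbilical cord, were profiled by RNA sequencing in 3 groups of 3 libraries. Control cells received a scramble siRNA and stayed in growth medium. TGFβ cells received the scramble siRNA and spent 5 days in a medium that contains TGFβ2 and induces endothelial-to-mesenchymal transition (EndMT), in which endothelial cells take on features of mesenchymal cells. The siACSS2 cells received an siRNA against ACSS2, the cytosolic and nuclear enzyme that makes acetyl-CoA from acetate, in the same induction medium. RNA was taken at 6 days, and each siRNA was used at 15 nM. The libraries held 27735299 to 34929323 estimated counts, of which the mitochondrial genome took 2.35 to 2.96%. Levels are CPM, the counts of a gene scaled to library size, given as mean ± SD with n = 3 libraries per group throughout. Values beside a gene name without a unit are log2 fold changes, and ± after a log2 value is the SE. Libraries of one group correlated at r = 0.985 to 0.996 across genes in log2 CPM. The first principal component held 65.8% of the variance and placed the TGFβ libraries at 59.9 to 61.3, the controls at -16.6 to -13.5 and the siACSS2 libraries at -47.7 to -43.9. The second held 21.8% and set the controls (34.8 to 35.6) apart from both other groups. The third, with 5.10%, set siACSS2 replicate 3 (29.2) apart from siACSS2 replicates 1 and 2 (-16.0 and -16.6). The labels name replicates without saying that they are separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

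The siRNA target was measured first. ACSS2 (chromosome 20, 33462766 to 33515770, plus strand, coordinates as the deposited table gives them, with the build not given in the sources used here) stood at 22.9, 23.9 and 22.7 CPM in control replicates 1 to 3, and at 14.8, 15.2 and 15.9 CPM in the TGFβ replicates. In siACSS2 replicates 1 to 3 it stood at 1.62, 1.76 and 1.32 CPM, from 55, 59 and 44 estimated counts. ACSS2 was 9.74-fold lower in siACSS2 than in TGFβ cells (log2 fold change -3.28 ± 0.095 SE, edgeR adjusted p = 6.22e-12) and 14.7-fold lower than in control cells (log2 -3.88 ± 0.091). In the RPM table, tested with limma, these log2 fold changes were smaller, -2.56 and -3.26. The induction medium alone changed it by a log2 fold change of -0.60 ± 0.069 (adjusted p = 8.78e-06). The groups did not overlap in any of the 3 comparisons, and an exact two-sided permutation test of 3 against 3 libraries gave 0.1, the smallest p it can give. Of 13 ACSS2 transcript models, 2 held enough counts to be tested, and both fell in siACSS2 against TGFβ cells, with log2 fold changes of -5.24 and -3.55.

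**Figure D1:**
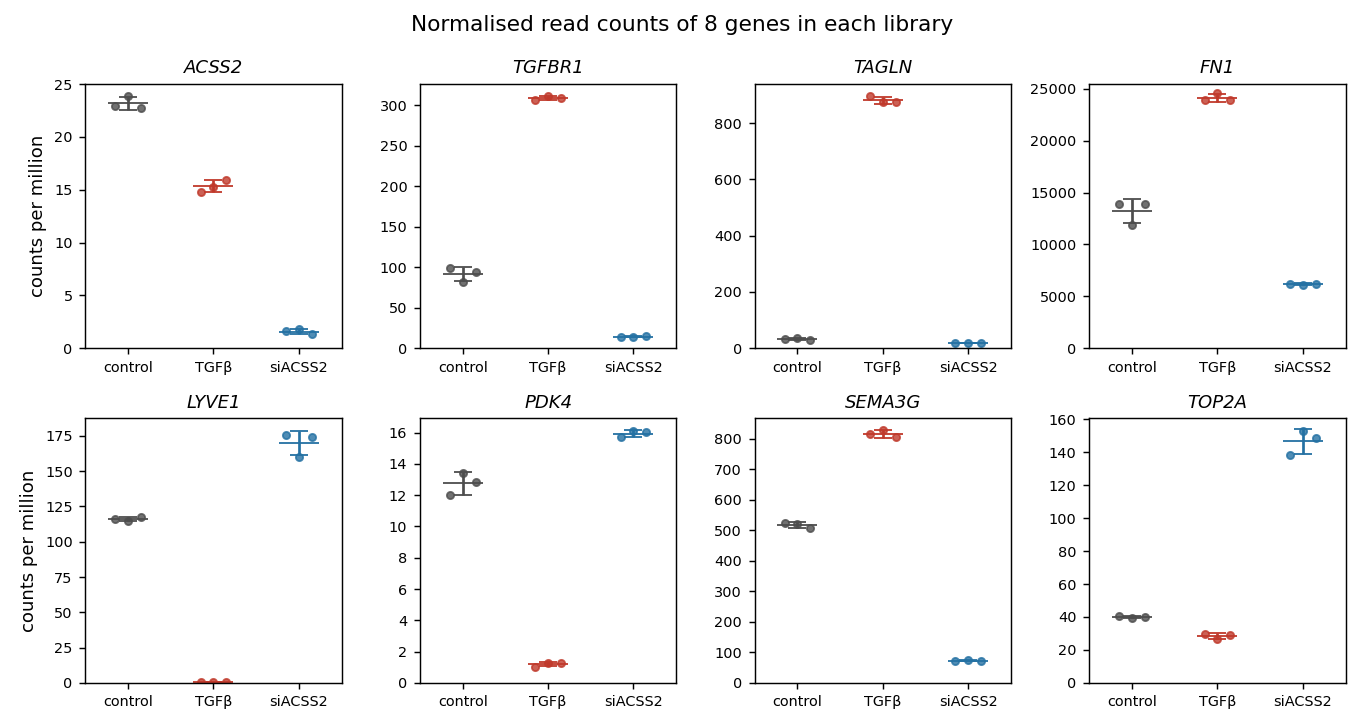
CPM (linear y axes from 0) of ACSS2, TGFBR1, TAGLN, FN1, LYVE1, PDK4, SEMA3G and TOP2A in the 9 libraries; points are single libraries, and horizontal lines with bars are the group mean ± SD of 3 libraries. ACSS2 falls from 15.3 CPM in TGFβ to 1.57 CPM in siACSS2 cells, TGFBR1 rises from 91.7 to 309 CPM in TGFβ cells and stands at 13.8 CPM in siACSS2 cells, and LYVE1 is near 0 in the TGFβ libraries only.

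The first comparison asks which genes moved when endothelial cells were placed in induction medium. Induction medium without TGFβ2 was not analysed here, so effects of TGFβ2 and of the rest of the medium cannot be told apart. Genes of the mesenchymal state and of TGFβ signalling rose, whereas endothelial, inflammatory and interferon genes fell. VCAN, which encodes the matrix proteoglycan versican (chromosome 5, 82767284 to 82878123, plus strand), went from 6 estimated counts over the 3 control libraries to 57371 over the 3 TGFβ libraries, a ratio of 11844 (95% interval 5441 to 32274). TAGLN, an actin-binding protein of contractile cells (chromosome 11, 117070037 to 117075499, plus strand), went from 31.8 ± 2.61 to 881 ± 13.3 CPM (log2 4.79 ± 0.060, adjusted p = 8.12e-15). LYVE1, a hyaluronan receptor of lymphatic and some venous endothelium (chromosome 11, 10578513 to 10590266, minus strand), went from 116 ± 1.32 to 0.514 ± 0.114 CPM (log2 -7.82 ± 0.091). With edgeR's quasi-likelihood test, 7320 of 13850 genes changed, 3488 up and 3832 down, and 539 and 811 of these by at least 2-fold. In 61.8% of genes the 2 groups did not overlap, against 10% by chance. Scaled by library totals alone, 2213 genes rose and 5670 fell, since this moved the median gene, by a log2 of -0.13; rises and falls are given relative to the main scaling. THBS1 took 3.01 to 3.32% of the counts in control, 4.01 to 4.15% in TGFβ and 1.84 to 1.93% in siACSS2 libraries.

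After VCAN, the largest rises were in AMPH (1.93 to 66.4 CPM), the integrin subunit ITGA4 (0.471 to 13.9), TAGLN, the keratin KRT7 (6.79 to 154), the matrix protein tenascin C, TNC (2.34 to 52.4), LTBP4 (4.81 to 106), GXYLT2 (0.712 to 14.7), CDH6 (0.919 to 17.2) and TGFBI (90 to 1493). After LYVE1, the largest falls were in ENPP2, which encodes autotaxin (20.1 to 0.234 CPM), the protease inhibitor A2M (62.9 to 1.34), MYRIP (5.23 to 0.128), the interferon-induced IFIT2 and IFIT1 (14.1 to 0.357 and 24.8 to 0.70), and H19, an imprinted noncoding RNA (3844 to 120.0). CPA3 (34.3 to 1.18), the chemokine CCL14 (11.4 to 0.45) and GALNT15 (16.3 to 0.65) followed. The log2 fold changes of these genes ranged from 4.05 to 5.09 among the rises after VCAN and from -6.39 to -4.65 among the falls after LYVE1, with SE between 0.037 and 0.31.

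TGFβ target and feedback genes rose as a group, with 21 of 26 tested members up and 1 down, CDKN1A at log2 -0.15 (camera adjusted p = 2.57e-27). List p-values are from camera, which sets a list against the other genes. Ranges given over the camera alternatives leave out fry, which tests a list on its own and passed 72 of the 84 list tests of the 3 comparisons, against 38 with camera. TGFBI rose by 4.05 ± 0.037, the NADPH oxidase NOX4 by 3.06 ± 0.059 and LTBP2 by 2.17 ± 0.042. The inhibitory SMAD7 rose from 10 ± 1.17 to 23.8 ± 1.47 CPM. Of 29 TGFβ and BMP pathway components, 17 rose and 7 fell (adjusted p = 1.13e-07). LTBP4, which binds latent TGFβ, TGFB2 itself (2.98) and LTBP1 (2.30) led the rises. The type I receptor gene TGFBR1 (chromosome 9, 101866320 to 101916475, plus strand) rose from 91.7 ± 8.73 to 309 ± 2.59 CPM, and the type II receptor gene TGFBR2 fell from 1885 ± 84.5 to 1091 ± 50.1 CPM. SMAD2, SMAD3 and SMAD4 did not pass the test, with log2 fold changes of 0.04 ± 0.038, -0.02 ± 0.049 and -0.08 ± 0.037. However, SMAD3 (-0.15 in both) and SMAD4 (-0.20 and -0.21) fell past the threshold under library totals and in the RPM table. RPM values are also scaled to library totals, so these are not separate checks of the scaling. BMP and SMAD1/5 targets rose in 8 of 10 cases (adjusted p = 0.000955), led by ID1 (1.92), SMAD6 (1.48) and HEY2 (0.78), and fell in 2, TMEM100 (-1.08) and HEY1 (-0.30).

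Mesenchymal and contractile genes rose in 21 of 28 cases and fell in 5 (adjusted p = 9.15e-16). TAGLN, tropomyosin TPM1 (1.86) and N-cadherin, CDH2 (163 ± 2.88 to 444 ± 3.71 CPM), had the smallest adjusted p, and the members that fell were NT5E, S100A6, TNS1, CDH13 and S100A4 (-2.53). CNN1, a smooth muscle calponin, went from 7 to 415 estimated counts over 3 libraries, a ratio of 73.4 (95% interval 35.3 to 184). ACTA2, smooth muscle actin, did not differ past the threshold (8.24 ± 0.121 and 8.2 ± 1.42 CPM, adjusted p = 0.979). VIM, vimentin, was already at 6125 ± 297 CPM in control cells and rose by 0.12 ± 0.033, a change that turned sign when scaled by library totals and in the RPM table. Extracellular matrix genes rose in 30 of 44 cases and fell in 12 (adjusted p = 3.49e-13, adjusted p = 0.051 with an estimated correlation, 9.39e-16 to 0.051 over the camera alternatives). Besides VCAN, MMP2 (2.03) and COL5A1 (2.41) led, fibronectin, FN1, rose from 13215 ± 1198 to 24129 ± 386 CPM, and the collagen gene COL1A2 from 6.12 ± 0.92 to 11.6 ± 1.3 CPM. Among EMT transcription factors, 6 of 11 rose and 1, YAP1 (-0.80), fell (adjusted p = 0.0383, adjusted p = 0.312 with an estimated correlation, 0.0114 to 0.312 over the camera alternatives), with FOXC2 at 1.23, SRF at 0.60 and SNAI1 at 1.26 (4.19 ± 0.241 to 10.1 ± 0.0938 CPM). COL1A1, SNAI2 and TWIST1 were not tested.

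Endothelial identity genes fell in 24 of 38 cases and rose in 10 (adjusted p = 0.000955). CD34, a surface marker of endothelium, fell by 3.60 ± 0.049 on the log2 scale, whereas EMCN (2.34) and the VEGF receptor FLT1 (1.84) rose. The receptor KDR fell from 1228 ± 89.4 to 651 ± 15.7 CPM, von Willebrand factor, VWF, from 4509 ± 278 to 2079 ± 40.8 CPM, and nitric oxide synthase NOS3 from 29 ± 0.613 to 12.1 ± 0.537 CPM. VE-cadherin, CDH5, fell from 2880.1 ± 64.5 to 2456 ± 17.5 CPM. PECAM1, tested only in the deposited RPM table with limma on log2(value + 1), fell from 2931 ± 117 to 1666 ± 16.4 RPM (log2 -0.81 ± 0.041). Of the 16 arterial and Notch genes, 8 rose, with SEMA3G (0.66), GJA5 (0.81) and HEY2 (0.78) first, and 5 fell, NRP1, UNC5B, CXCR4, NOTCH4 and HEY1 (list adjusted p = 0.228). The venous and lymphatic list fell (adjusted p = 0.0274, adjusted p = 0.112 with an estimated correlation, 0.00673 to 0.895 over the camera alternatives), with LYVE1, NR2F2 (-0.55) and PROX1 (-0.62) down and NRP2 (1.36) and ACKR1 (1.28, a call lost in the RPM table) up among 6 members. FGF and VEGF signalling genes rose in 10 and fell in 6 of 18 cases (adjusted p = 0.287), with ETV5 at 1.15, ETV1 at 0.98 and DUSP5 at -1.16, and FGFR1 fell from 179.9 ± 1.69 to 146 ± 4.04 CPM.

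Every one of the 29 tested interferon response genes fell (adjusted p = 5.08e-38), with a median log2 of -2.98, with BST2 at -1.76, OAS3 at -3.85 and OAS2 at -4.28. Endothelial inflammation genes fell in 18 of 22 cases (adjusted p = 4.28e-19). E-selectin, SELE, fell by 3.69, the cytokine IL33 at -3.29, ICAM1 from 341 ± 2.42 to 71.1 ± 3.38 CPM and VCAM1 from 108 ± 4.81 to 82.3 ± 1.78 CPM, whereas PTGS2 (2.38), TLR4 (0.33) and IL1A (0.43) rose. Cell cycle genes fell in 23 of 36 cases, with a median of -0.42, and 1, CDC6 (0.49), rose (adjusted p = 0.021, adjusted p = 0.431 with an estimated correlation, 0.000763 to 0.431 over the camera alternatives); FOXM1 fell by 1.10, KIF20A at -0.68 and TOP2A at -0.50.

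Among metabolic genes, 14 of 27 acetate and acetyl-CoA genes fell and 7 rose, without the list passing the test (adjusted p = 0.112). PDK4, which restrains pyruvate entry into the mitochondrial acetyl-CoA pool, fell from 12.8 ± 0.718 to 1.2 ± 0.156 CPM, the mitochondrial acetyl-CoA synthetase ACSS1 from 34.1 ± 0.636 to 10.2 ± 0.488 CPM, and ACSS3 at -1.97. ATP-citrate lyase, ACLY, rose from 249 ± 7.55 to 305 ± 1.26 CPM, PDHA1 fell by 0.18 ± 0.045, and ACACA did not pass (-0.05 ± 0.052). It fell past the threshold without control replicate 2 (-0.11, adjusted p = 0.0204), under library totals (-0.18) and in the RPM table (-0.17). Fatty acid oxidation genes fell in 10 of 16 cases, CPT1A at -1.39 and CPT1C at -1.12, and 1, PPARD (0.45), rose (adjusted p = 0.0369, adjusted p = 0.195 with an estimated correlation, 0.00787 to 0.195 over the camera alternatives). Cholesterol genes fell in 13 of 23 cases, short of the threshold for the list (adjusted p = 0.0794, 0.0127 to 0.197 over the camera alternatives). The glycolysis (7 up and 7 down of 21, PFKP 1.14), fatty acid synthesis (6 up of 15, ACSL4 0.94), TCA and respiratory chain (11 down of 28), hypoxia (6 up of 14), stress response (10 down of 23, VLDLR -1.43) and acetyltransferase (11 down of 26, KAT7 -1.09) lists did not pass either, with adjusted p between 0.095 and 0.914.

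Markers of other cell types were few, and members of each list went both ways. NOTCH3 rose from 33 to 1102 estimated counts, and RGS5 (0.34) and SYNPO2 (1.09) rose with it while SMTN (-0.19) fell, in a smooth muscle and pericyte list of 4 tested genes (adjusted p = 0.0475, adjusted p = 0.157 with an estimated correlation, 0.0325 to 0.675 over the camera alternatives). That call was lost without control replicate 1 or 2 and without any TGFβ library. In the latter case NOTCH3 was no longer tested, as it reached 1 CPM only in the 3 TGFβ libraries. CD14 (3.18) and LAPTM5 (0.63) rose and CD68 (-1.18) fell in the leukocyte list of 3 (adjusted p = 0.008, adjusted p = 0.103 with an estimated correlation, 0.00338 to 0.103 over the camera alternatives). In the fibroblast list of 3, PDGFRA rose (0.86), CLEC3B fell (-3.29), and THY1 went from 126 to 2 estimated counts, a ratio of 50.9 (95% interval 13.8 to 425) (list adjusted p = 0.207). The epithelial list had too few tested members. The RNA quality lists had median log2 fold changes of 0.09 (mitochondrial genome), 0.26 (immediate early and heat shock) and -0.05 (ribosomal proteins), with adjusted p of 0.366, 0.228 and 0.685; the mean of the immediate early list had the other sign (-0.02). Adjusted over the list alone, all lists had the counts given above except TGFβ and BMP pathway components (18 rose, 7 fell), venous and lymphatic (3 rose, 3 fell), fatty acid synthesis and desaturation (6 rose, 6 fell), cell cycle and proliferation (2 rose, 23 fell), hypoxia targets (7 rose, 5 fell), ribosomal proteins (0 rose, 5 fell). In simulated data with known changes, 58% of 1.5-fold, 92% of 2-fold and 98% of 4-fold changes were recovered for this comparison.

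**Figure D2:**
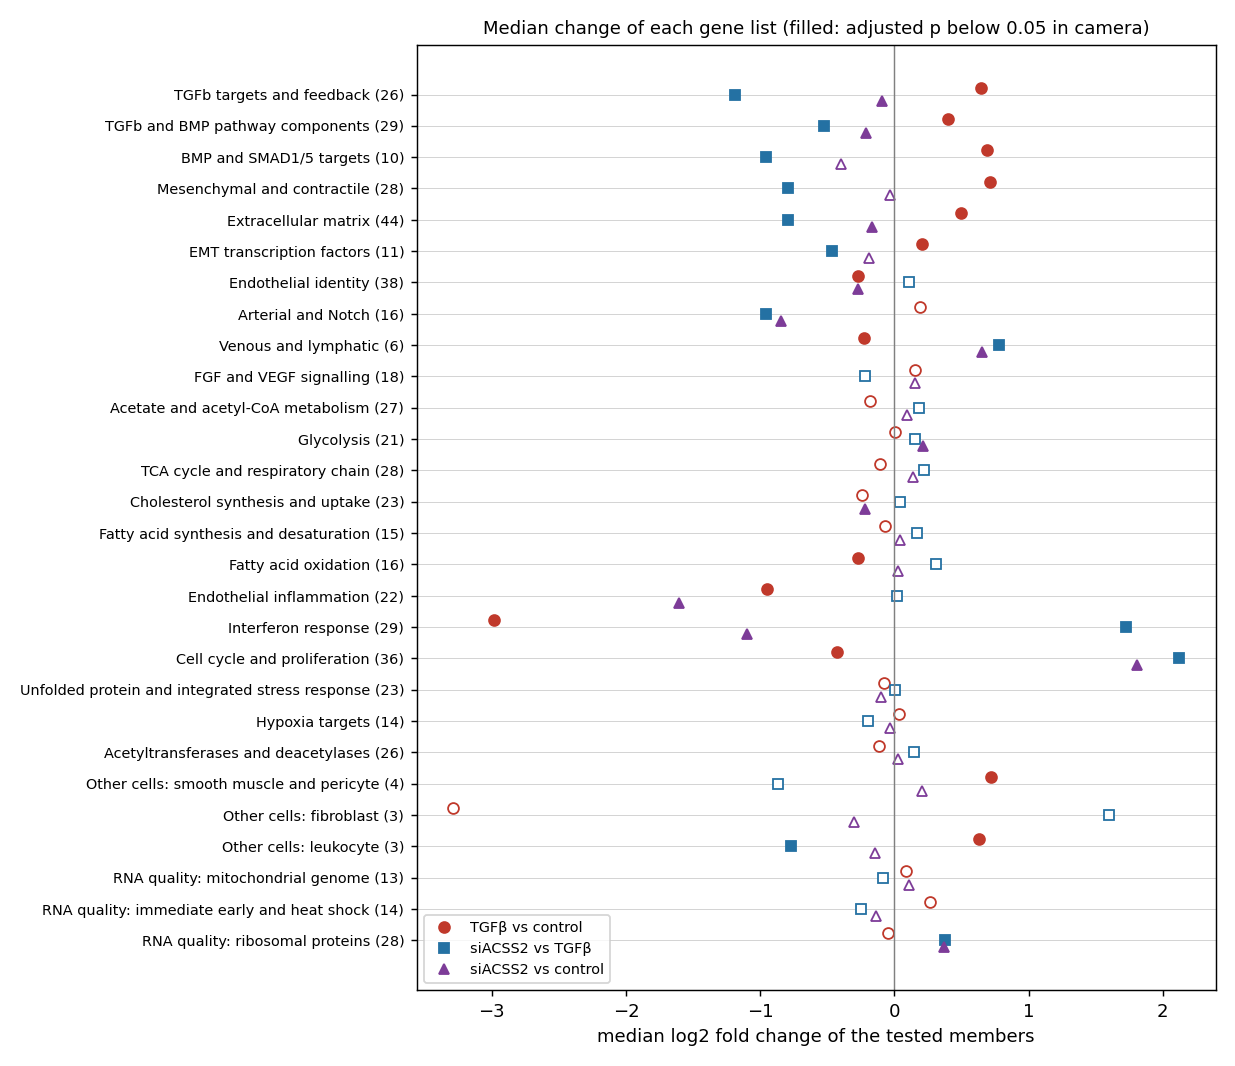
Median log2 fold change (x axis) of the tested members of 28 gene lists (y axis, number of members tested in brackets) in the 3 comparisons; filled symbols passed camera at an adjusted p below 0.05 with a preset correlation, and open symbols did not. The TGFβ, mesenchymal and matrix lists lie right of 0 in TGFβ against control and left of 0 in siACSS2 against TGFβ cells, and cell cycle genes have medians of 2.12 and 1.81 in the siACSS2 comparisons.

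The second comparison asks what ACSS2 siRNA changed in cells kept in induction medium. TGFβ target, mesenchymal, matrix and arterial genes fell, and cell cycle genes rose. Lymphatic and interferon genes rose less firmly, as the venous and lymphatic call was lost with limma-voom (adjusted p = 0.151) and in the RPM table (0.229), and the interferon call with an estimated correlation (0.268). VCAN went from 57371 to 54 estimated counts over 3 libraries, a ratio of 1327 (95% interval 1017 to 1766). TAGLN fell from 881 ± 13.3 to 18.4 ± 0.807 CPM (log2 -5.58 ± 0.063, adjusted p = 2.24e-15), and LYVE1 rose from 0.514 ± 0.114 to 170.1 ± 8.47 CPM. TGFBR1 fell from 309 ± 2.59 to 13.8 ± 0.608 CPM, 22.4-fold (log2 -4.49 ± 0.070, adjusted p = 4.23e-14). In all, 9417 of 13850 genes changed, 5071 up and 4346 down, and 1244 and 936 of these by at least 2-fold. The groups did not overlap in 72% of genes, against 10% by chance. Scaled by library totals alone, 7931 genes rose and 2545 fell, with the median gene moved by 0.26 log2. Without siACSS2 replicate 3, the library apart on the third principal component, 9094 genes changed.

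The largest rises after LYVE1 were in MYRIP (0.128 to 14.6 CPM), the chemokine CXCL6 (0.359 to 33.4), A2M (1.34 to 105), CCL14 (0.45 to 25.3), ENPP2 (0.234 to 8.98), the chemokine CXCL8 (1.0 to 28), CPA3 (1.18 to 31.2), GALNT15 (0.65 to 16.6) and MALL (8.71 to 189.7). The largest falls after VCAN were in TNC (52.4 to 0.278 CPM), AMPH (66.4 to 0.973), LTBP4 (106 to 1.68), GXYLT2 (14.7 to 0.287), TAGLN, PROM1 (22.7 to 0.527), NHS (43.9 to 1.37), CD14 (37.8 to 1.33) and the metalloprotease ADAM12 (16.9 to 0.687). Their log2 fold changes ran from 4.44 to 6.83 for the rises after LYVE1 and from -7.54 to -4.61 for the falls after VCAN.

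None of the 26 TGFβ target and feedback genes rose and 22 fell (adjusted p = 5.51e-25), TGFBI at -3.68, CCN2 at -1.81, PMEPA1 at -2.50 and SMAD7 at -1.84. That none rose depends on the scaling, since CDKN1A rose with upper quartile factors (0.13, adjusted p = 0.0223), and 3 members, CDKN1A among them (0.33 and 0.34), rose under library totals and in the RPM table. Pathway components fell in 20 of 29 cases and rose in 7 (adjusted p = 1.14e-10), LTBP4 at -5.98, the activin subunit INHBA at -4.33 and TGFBR1 as above. TGFBR2 (0.60 ± 0.043) and SMAD3 (0.55 ± 0.048) rose, and SMAD2 (-0.25 ± 0.038) and SMAD4 (-0.19 ± 0.037) fell, the last pair with the other sign when scaled by library totals and in the RPM table. BMP and SMAD1/5 targets fell in 8 of 10 cases (adjusted p = 0.000151), with CCN1 at -1.04, SMAD6 at -2.06 and HEY2 at -0.99, and TMEM100 rose, as did GATA2 (0.16 ± 0.066), whose call was lost under 10 of 19 alternatives, among them without TGFβ replicate 1, 2 or 3 (0.0526, 0.0802 and 0.149) or siACSS2 replicate 1 or 2 (0.132 and 0.0883) (adjusted p in brackets). Mesenchymal and contractile genes fell in 20 of 28 cases and rose in 7 (adjusted p = 1.17e-08), TPM1 at -2.72, MYL9 at -2.49 and CDH2 from 444 ± 3.71 to 216 ± 5.95 CPM. CNN1 had 0 estimated counts in the siACSS2 libraries, at least 173-fold lower than in TGFβ cells against a floor of 3 counts over the group. ACTA2 rose from 8.2 ± 1.42 to 16.8 ± 0.965 CPM, and VIM fell by 0.21 ± 0.033, a fall that turned sign under library totals and in the RPM table. Matrix genes fell in 31 of 44 cases and rose in 12 (adjusted p = 1.51e-13), BGN at -2.04, TNC at -7.54 and FN1 from 24129 ± 386 to 6179 ± 72.2 CPM, while COL1A2 rose from 11.6 ± 1.3 to 19.7 ± 0.718 CPM. EMT transcription factors fell in 8 of 11 cases (adjusted p = 0.0273, adjusted p = 0.354 with an estimated correlation, 0.00456 to 0.354 over the camera alternatives), FOXC2 at -1.70, SRF at -0.79, TCF4 at -0.47 and SNAI1 at -0.80, and 1, ZEB1 (0.30), rose.

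All 36 cell cycle genes rose (adjusted p = 5.26e-38), with a median log2 of 2.12, with FOXM1 at 2.86, the ribonucleotide reductase subunit RRM2 at 2.15 and topoisomerase TOP2A at 2.37 (28.4 ± 1.75 to 147 ± 7.52 CPM). Arterial and Notch genes fell in 13 of 16 cases (adjusted p = 4.57e-13), SEMA3G at -3.48, the gap junction gene GJA5 at -2.95 and the Notch ligand DLL4 at -2.08, and NRP1, UNC5B and CXCR4 rose, each by 0.40. Venous and lymphatic genes rose in 4 of 6 cases (adjusted p = 8.71e-05, 3.23e-06 to 0.229 over the camera alternatives), LYVE1, NR2F2 (1.81), PROX1 (1.21) and EPHB4 (0.14), and NRP2 fell (-0.64). The endothelial identity list as a whole did not pass (19 up and 15 down of 38, adjusted p = 0.416). CD34 (2.87), NOS3 (12.1 ± 0.537 to 48 ± 4.0 CPM), KDR (0.70) and VWF (0.28) rose, and FLT1 (-2.15) and FLT4 (-2.0) fell. CDH5 fell by 0.27 ± 0.031, with the call lost under library totals and the other sign in the RPM table, and PECAM1 rose there by 0.18 ± 0.041, with the other sign once that table was scaled by TMM or DESeq2 factors.

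Interferon response genes rose in 26 of 29 cases, with a median log2 of 1.73, and 1, CMPK2 (-0.47), fell (adjusted p = 1.94e-07, adjusted p = 0.268 with an estimated correlation, 1.34e-10 to 0.268 over the camera alternatives), with OAS3 at 3.14, OAS2 at 3.32 and BST2 at 1.14. The CMPK2 call was lost under 4 of 19 alternatives, among them without TGFβ replicate 2 (0.0736) or siACSS2 replicate 2 (0.0648) (adjusted p in brackets). Endothelial inflammation genes split, 10 up and 8 down of 22 (adjusted p = 0.993); PTGS2 (-3.03) and VCAM1 (82.3 ± 1.78 to 24.1 ± 1.6 CPM) fell, and CXCL8 (4.78) and ICAM1 (0.46) rose. PDK4 rose from 1.2 ± 0.156 to 15.9 ± 0.213 CPM, ACSS1 by 0.86, PDHA1 by 0.45 and ACACA by 0.19, while PDP1 fell by 0.99. ACLY fell by 0.26, with the call lost under library totals and the other sign in the RPM table. The acetate list rose in 15 and fell in 8 of 27 cases (adjusted p = 0.362). TCA and respiratory chain genes rose in 20 of 28 cases, with OGDH at 0.76, FH at 0.85 and SDHA at 0.63, and IDH2 (-0.58) and DLST (-0.25, with the other sign under library totals and in the RPM table) fell (adjusted p = 0.0761, 0.00674 to 0.589 over the camera alternatives). Fatty acid oxidation genes rose in 11 of 16 cases, with CPT1A at 1.01 (adjusted p = 0.0867, 0.0188 to 0.354 over the camera alternatives). Glycolysis genes rose in 11 of 21, with PKM at 1.36 and LDHA at 1.21 (adjusted p = 0.182). The cholesterol (11 up, 7 down, SC5D -2.03), fatty acid synthesis (8 up, ACSL4 -0.75), FGF and VEGF (10 down, DUSP5 2.07), hypoxia (6 up, 8 down), stress response (8 up, 7 down, DDIT4 1.31) and acetyltransferase (12 up, KAT7 1.58) lists did not pass, with adjusted p between 0.192 and 0.91. FGFR1 fell by 0.15 ± 0.038, with the call lost under upper quartile factors and the other sign under library totals and in the RPM table.

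Ribosomal protein genes, kept as a check of RNA quality and reads shared with pseudogenes, rose in 26 of 28 cases with a median of 0.37 (adjusted p = 0.00164, adjusted p = 0.589 with an estimated correlation, 3.65e-06 to 0.589 over the camera alternatives), with RPS2 at 0.90, RPSA at 1.20 and RPS3 at 0.69. Pseudogenes took 2.58 to 3.04% of counts in siACSS2, 1.95 to 2.00% in TGFβ and 2.15 to 2.34% in control libraries. Whether this is linked to the rise of ribosomal protein genes was not tested. The mitochondrial genome and immediate early lists had medians of -0.09 and -0.25 (adjusted p = 0.922 and 0.2), with IER3 at -1.46 and EGR1 at 1.94. In the leukocyte list CD14 (-4.82) and LAPTM5 (-0.77) fell and CD68 (2.68) rose (adjusted p = 0.023, adjusted p = 0.217 with an estimated correlation, 0.019 to 0.264 over the camera alternatives). In the smooth muscle list NOTCH3 (-5.17) and SYNPO2 (-2.14) fell and RGS5 (0.99) and SMTN (0.41) rose (adjusted p = 0.79). In the fibroblast list PDGFRA (-1.16) fell, CLEC3B (1.60) rose and THY1 went from 2 to 447 estimated counts, a ratio of 179 (95% interval 49.3 to 1482) (adjusted p = 0.416). Adjusted over the list alone, the counts differed only for EMT transcription factors (1 rose, 9 fell), interferon response (27 rose, 1 fell), acetyltransferases and deacetylases (11 rose, 4 fell), ribosomal proteins (27 rose, 0 fell). For this comparison, simulated changes of 1.5, 2 and 4-fold were recovered in 76%, 86% and 96% of cases.

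Most genes that moved in both comparisons moved in opposite directions. Of 5971 genes called in both, 5373 (90%) had opposite signs, 2562 that rose in TGFβ cells and fell with ACSS2 siRNA and 2811 that fell and then rose, and 598 kept one direction. The receptor gene TGFBR1 stood at 13.8 CPM in the siACSS2 cells, against 309 CPM in TGFβ cells, and cells with another ACSS2 siRNA were not analysed here, so these opposite changes were not separated into those that follow loss of ACSS2 and those that follow loss of TGFBR1. Besides VCAN and LYVE1, the genes at the top of this ranking were near 0 counts in control and siACSS2 cells or in TGFβ cells. GLI2, a transcription factor of hedgehog signalling, had 0, 120 and 0 estimated counts in control, TGFβ and siACSS2 cells, at least 49.5-fold higher in TGFβ than in control cells and at least 50-fold lower in siACSS2 than in TGFβ cells. The netrin receptor gene DCC had 3, 735 and 1 counts (ratios 303 (95% interval 103 to 1475) and 918 (95% interval 164 to 36304)). The glypican GPC4 had 0, 278 and 1, at least 115-fold higher and then lower by a ratio of 347 (95% interval 61.8 to 13761). C5orf46 had 5, 679 and 0 counts (a ratio of 168 (95% interval 71.7 to 519.7), then at least 283-fold lower). The bradykinin receptor BDKRB2 had 3, 663 and 7 (ratios 274 (95% interval 93.3 to 1331) and 118 (95% interval 57.1 to 295)). SLIT3 had 5, 330 and 3 (ratios 81.8 (95% interval 34.7 to 253) and 137 (95% interval 46.6 to 669.5)). PRND went the other way with 369, 1 and 215 counts (ratios 298 (95% interval 53.1 to 11798) and 172 (95% interval 30.6 to 6831)), as did PLA1A with 51, 0 and 171, at least 13.7-fold lower and then at least 45.6-fold higher. These intervals cover counting error only, and the bounds take the higher count as exact. Reads without molecular identifiers are not independent molecules.

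Both comparisons use the same 3 TGFβ libraries, so chance in these pushes them apart. In 20 simulated sets of 3 unchanged groups, a mean of 0.1 genes (0 to 1) was called in opposite directions, and independent lists of these sizes would share 2498. The log2 fold changes correlated at r = -0.789 across genes, which are not independent replicates, against -0.513 in the simulations (from -0.534 to -0.483). Their covariance was -0.604, against -0.0105 in the simulations, a difference of -0.594. The 3 TGFβ libraries cannot be divided into 2 sets of 2 or more, so opposite calls could not be tested on separate libraries. The simulated covariance argues against the spread among these libraries as the source of most of the observed covariance. The simulated count says little about opposite calls, since no gene differed between the groups there and few could be called at all. The figure of 2498 for independent lists takes no account of the shared libraries. A deviation common to all 3 TGFβ libraries was not simulated and may add to both the covariance and the count. Of the 3488 genes that rose in TGFβ cells, 1154 did not differ from control past the threshold with ACSS2 siRNA, 1065 were still above control and 1269 were below it. Of the 3832 that fell, 1290 did not differ from control, 1436 were still below it and 1106 were above it.

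**Figure D3:**
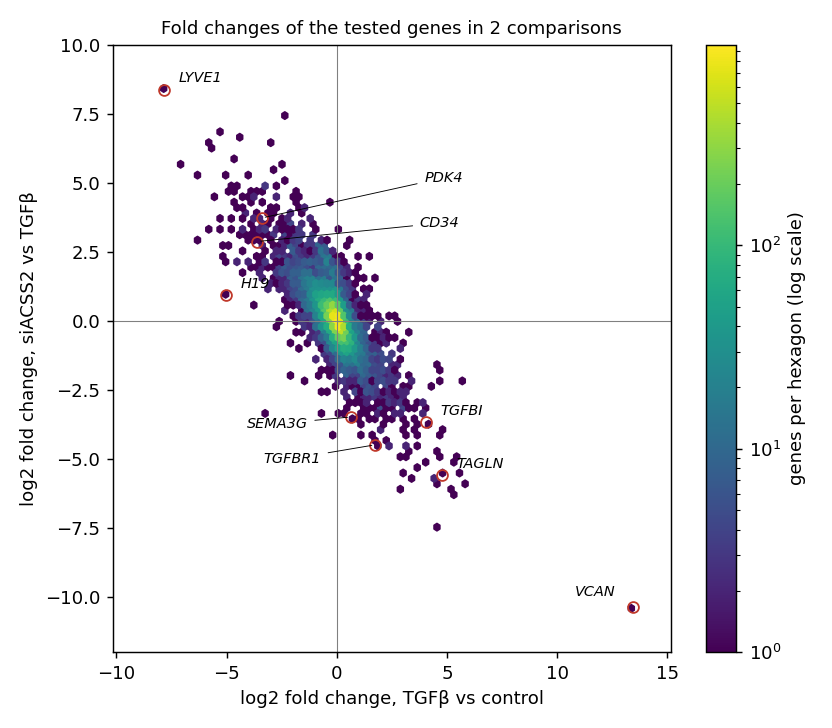
Log2 fold change in siACSS2 against TGFβ cells (y axis) plotted against that in TGFβ against control cells (x axis) for 13821 genes; colour gives the number of genes per hexagon on a log scale, circles mark 9 named genes, and 29 genes with 3 or fewer counts in a group are left out. Genes lie along a falling diagonal (r = -0.789 over all 13850 genes), with VCAN at 13.44 and -10.36 and LYVE1 at -7.82 and 8.37, while TGFBR1 (1.75, -4.49) and SEMA3G (0.66, -3.48) fall further than they rose and H19 (-5.0, 0.92) recovers least of those named.

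The third comparison asks how cells with ACSS2 siRNA in induction medium stood against control cells in growth medium. Cell cycle genes were higher than in control cells, and arterial, Notch and inflammation genes were lower. Glycolysis and lymphatic genes were also higher and interferon genes lower, but these 3 calls were lost with an estimated correlation (adjusted p = 0.268, 0.0683 and 0.0985). SEMA3G, a semaphorin of arterial endothelium (chromosome 3, 52467069 to 52479102, minus strand), stood at 518 ± 9.16 CPM in control and 73.1 ± 0.711 CPM in siACSS2 cells (log2 -2.82 ± 0.036, adjusted p = 5.06e-14). TGFBR1 stood 6.66-fold below control (log2 -2.73 ± 0.068, adjusted p = 8.98e-12), in contrast to its rise in TGFβ cells. In all, 8070 of 13850 genes differed, 4046 up and 4024 down, and 612 and 476 of these by at least 2-fold. The groups did not overlap in 62% of genes, against 10% by chance. Scaled by library totals alone, 5829 genes were higher and 2720 lower, with the median gene moved by 0.13 log2. Without siACSS2 replicate 3, 7778 genes differed. This comparison changes both the medium and the siRNA, and cells with ACSS2 siRNA in growth medium were not analysed here.

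The largest rises were in SPOCD1 (1.84 to 18.9 CPM), RPS4XP3, VCAN (6 to 54 estimated counts, a ratio of 8.93 (95% interval 3.85 to 25.4)), APCDD1L (2.03 to 14.8 CPM), KRT7 (6.79 to 49.8), the keratin KRT19 (3.75 to 24.6), ADAMTS4 (3.02 to 18.9), FAM111B (2.53 to 14.2), INSYN2B (3.28 to 18.3) and the neurotrophin receptor NTRK2 (2.8 to 15.7). The value of RPS4XP3, a pseudogene with near-identical copies, rested on siACSS2 replicate 3, with a log2 fold change of 3.27 ± 0.87 with that library and 0.91 without it, and its call was lost with limma-voom (adjusted p = 0.137). The largest falls were in CD69 (17.1 to 0.934 CPM), the imprinted growth factor IGF2 (2226 to 126), H19 (3844 to 227), ACSS2, the Notch target HES4 (11.1 to 1.21), SELE (83.1 to 9.14), TNC (2.34 to 0.278), ABCA4 (30 to 3.93), SEMA3G and COL15A1 (55.2 to 8.02). IGF2 had also fallen to 535 CPM in TGFβ cells.

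Every one of the 36 cell cycle genes was higher than in control (adjusted p = 1.57e-63), with a median log2 of 1.81, with RRM2 at 1.81, KIF20A at 2.22 and TOP2A at 1.87. Of 16 arterial and Notch genes, 15 were lower and none higher (adjusted p = 1.58e-21), GJA5 at -2.14 and DLL4 at -1.68. However, NRP1 was higher under library totals (0.092) and in the RPM table (0.11) and lower past the threshold without control replicate 2 (-0.076, adjusted p = 0.0474). All 6 venous and lymphatic genes were higher (adjusted p = 0.000965, adjusted p = 0.0683 with an estimated correlation, 4.97e-05 to 0.0683 over the camera alternatives), NR2F2 by 1.26, NRP2 by 0.72 and LYVE1 by 0.55. Endothelial inflammation genes were lower in 20 of 22 cases and 1, CXCL8 (0.82), was higher (adjusted p = 2.54e-27), with SELE at -3.18, ICAM1 at -1.80 and VCAM1 at -2.17. Interferon genes were lower in 28 of 29 cases (adjusted p = 4.12e-16, adjusted p = 0.0985 with an estimated correlation, 3.57e-24 to 0.0985 over the camera alternatives), with ISG15 at -1.36, IFIT3 at -1.72 and IFIT2 at -1.85. Endothelial identity genes were lower in 24 of 38 cases and higher in 12 (adjusted p = 0.016, adjusted p = 0.0869 with an estimated correlation, 0.000697 to 0.0869 over the camera alternatives), FLT4 at -1.62, CD93 at -0.70 and CD34 at -0.73. VWF (-0.84), CDH5 (-0.50), KDR (-0.21) and FGFR1 (-0.44) were lower, KDR without passing the test under library totals and in the RPM table, NOS3 was higher (0.72), and PECAM1 was lower in the RPM table (-0.64 ± 0.041).

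TGFβ target genes were higher in 8 and lower in 12 of 26 cases (adjusted p = 0.016, adjusted p = 0.0877 with an estimated correlation, 0.00282 to 0.16 over the camera alternatives), with CCN2 at -1.13, ESM1 at -1.65 and SMAD7 at -0.59. Pathway components were lower in 16 of 29 cases (adjusted p = 0.000205, adjusted p = 0.0781 with an estimated correlation, 1.61e-06 to 0.0781 over the camera alternatives), TGFBR1 most, INHBA at -2.05, TGFBR2 at -0.19, SMAD2 at -0.21 and SMAD4 at -0.26. The members that were higher were the activin antagonist FST (2.33), SMAD3 (0.53), SMAD1, TGFB3 and ZFYVE9. The calls of TGFBR2 and SMAD2 were lost under library totals and in the RPM table, and that of ZFYVE9 was lost under 3 of 19 alternatives, among them without control replicate 3 (0.0614) or siACSS2 replicate 1 (0.0604) (adjusted p in brackets). Matrix genes were lower in 24 and higher in 11 of 44 cases (adjusted p = 0.0221, adjusted p = 0.563 with an estimated correlation, 0.00244 to 0.563 over the camera alternatives), with SPARC at -0.95, COL15A1 at -2.78 and FN1 at -1.10, while COL1A2 was higher (1.69). Mesenchymal genes were split, 12 higher and 12 lower of 28 (adjusted p = 0.776), with CDH13 at 1.32, TPM1 at -0.86, CALD1 at -0.66, TAGLN at -0.79, CDH2 at 0.41 and ACTA2 at 1.03. CNN1, with 7 counts in control and 0 in siACSS2 cells, was 2.35-fold lower against a floor of 3 counts over the group. That value leaves out the counting error of the 7 counts. The call was lost with limma in the RPM table (log2 -0.11, adjusted p = 0.377), where adding 1 to each value limits the change at such low levels. VIM was lower (-0.09 ± 0.033). It had the other sign, without passing the test, under library totals and in the RPM table. Its call was lost under a further 9 of 19 alternatives, adjusted p in brackets. Among these were fits without control replicate 2 (0.0679), TGFβ replicate 1, 2 or 3 (0.0556, 0.0528 and 0.0564) or siACSS2 replicate 1 or 3 (0.117 and 0.105). The EMT factor list did not pass (7 lower of 11, MRTFB at -0.75, YAP1 at -0.68 and FOXC2 at -0.47, with ZEB2, WWTR1, SNAI1 (0.46) and ZEB1 higher; adjusted p = 0.527). BMP targets did not pass either (7 lower of 10, CCN1 at -0.71 and HEY1 at -1.22, adjusted p = 0.137).

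Glycolysis genes were higher in 14 of 21 cases, LDHA by 1.14 and PKM by 0.97 (adjusted p = 0.000487, adjusted p = 0.268 with an estimated correlation, 4.64e-05 to 0.268 over the camera alternatives). Ribosomal protein genes were higher in 26 of 28, RPSA by 0.94, RPL4 by 0.44 and RPL5 by 0.45 (adjusted p = 4.16e-05, adjusted p = 0.563 with an estimated correlation, 1.21e-08 to 0.563 over the camera alternatives). Cholesterol genes were lower in 12 of 23 cases (adjusted p = 0.0123, adjusted p = 0.122 with an estimated correlation, 0.00109 to 0.122 over the camera alternatives), SC5D at -1.46 and INSIG1 at -1.17. In the acetate list 12 of 27 genes were higher and 5 lower (adjusted p = 0.877), the lower ones being ACSS2, ACSS1 (-0.89), PDP1 (-0.65), SLC16A3 and ACACB. PDK4 (0.32), PDHA1 (0.26) and ACACA (0.14) were higher. The ACACA call was lost under 9 of 19 alternatives, among them without control replicate 2 (0.102), TGFβ replicate 1, 2 or 3 (0.0529, 0.0513 and 0.053) or siACSS2 replicate 1 or 3 (0.0506 and 0.0718) (adjusted p in brackets). The ACACB call was lost under 4 of 18 alternatives, among them without control replicate 1 (0.0979) or siACSS2 replicate 2 (0.0774), and that of SLC16A3 was lost under 4 of 19 alternatives, among them without siACSS2 replicate 1 (0.063). ACLY did not pass (0.03 ± 0.038). It was higher past the threshold under library totals (0.16) and in the RPM table (0.17). TCA and respiratory chain genes were higher in 14 of 28 cases and lower in none, FH by 0.64 (adjusted p = 0.0599, 0.00208 to 0.7 over the camera alternatives). The remaining lists, FGF and VEGF (9 higher of 18, EGR1 1.40), fatty acid synthesis (6 higher and 6 lower of 15, ACSL1 0.71), stress response (11 lower of 23), immediate early (7 lower of 14), mitochondrial genome (6 higher of 13), fatty acid oxidation, hypoxia, acetyltransferases and the smooth muscle, fibroblast and leukocyte markers, did not pass, with adjusted p between 0.125 and 0.97. Their medians lay between -0.30 and 0.21. Adjusted over the list alone, the counts differed only for glycolysis (15 rose, 2 fell), endothelial inflammation (2 rose, 20 fell), interferon response (0 rose, 29 fell), acetyltransferases and deacetylases (3 rose, 3 fell). For this comparison, simulated changes of 1.5, 2 and 4-fold were recovered in 68%, 96% and 98% of cases.

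At the level of transcript models, estimated counts were tested for 35890 models. Of these, 5164 changed in TGFβ against control cells, 9420 in siACSS2 against TGFβ cells and 5839 in siACSS2 against control cells. The last count fell to 3884 without control replicate 1 and to 3887 without control replicate 3.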

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

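Comparison A is TGFβ against control, B siACSS2 against TGFβ and C siACSS2 against control. The alternatives with the RPM table in place of the counts were chosen after seeing the data, and the others, among them those for PECAM1 within the RPM table, were fixed before. The counts of genes changed stayed within 1.5 times of the main counts under every alternative except a 2-fold minimum, which left 1350, 2180 and 1088 genes. With 1 library left out at a time they were 6438 to 7576, 8610 to 9624 and 7258 to 7970, and genes with opposite changes were 4695 to 5370. The ACSS2 log2 fold change in comparison B lay between -3.37 and -3.17 with a library left out, and was -3.03 with library totals alone. In the RPM table it was -2.56, where adding 1 to each value limits the change at such low levels. Transcript models changed were 3540 to 7183, 6928 to 10170 and 3884 to 6729, the last falling to 3884 and 3887 without control replicates 1 and 3. In the RPM table, 2196 genes rose and 5726 fell, 7662 rose and 2433 fell, and 5687 rose and 2607 fell. Of 84 list tests, 38 passed in the main test, 18 with an estimated correlation and 72 with fry, which tests each list on its own and is left out of the ranges of adjusted p. With a library left out, 36 to 40 passed. DESeq2 was not run on the lists, and the pseudocounts apply only to PECAM1. Without a TGFβ library, 10 named genes fell below the filter and have no value.

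Adjusted p of list calls lost with an estimated correlation were, comparison A cell cycle 0.431, EMT factors 0.312, matrix 0.051, fatty acid oxidation 0.195, leukocyte 0.103, smooth muscle 0.157, venous 0.112, and comparison B EMT factors 0.354, interferon 0.268, leukocyte 0.217, ribosomal proteins 0.589, and comparison C cholesterol 0.122, endothelial identity 0.0869, matrix 0.563, glycolysis 0.268, interferon 0.0985, ribosomal proteins 0.563, pathway components 0.0781, TGFβ targets 0.0877, venous 0.0683. Calls lost without a filter on low counts were, comparison A smooth muscle 0.0524, and comparison B leukocyte 0.126. Calls gained without a filter on low counts were, comparison A acetate 0.0487, acetyltransferases 0.0467, cholesterol 0.0197, stress response 0.0388, and comparison B fatty acid oxidation 0.0406, TCA 0.0379, and comparison C TCA 0.0388. Calls lost with a minimum of 5 CPM in 3 libraries were, comparison A EMT factors 0.0549, fatty acid oxidation 0.0549, and comparison B EMT factors 0.0515. Calls gained with a minimum of 5 CPM in 3 libraries were, comparison C smooth muscle 0.0494. Calls gained with upper quartile factors were, comparison C TCA 0.0404. Calls lost with library totals alone were, comparison A EMT factors 0.0609, and comparison B EMT factors 0.0572, and comparison C endothelial identity 0.0523. Calls gained with library totals alone were, comparison A cholesterol 0.0488, and comparison B fatty acid oxidation 0.0449, TCA 0.0186, and comparison C TCA 0.0249. Calls lost with limma-voom were, comparison A leukocyte 0.101, smooth muscle 0.139, venous 0.895, and comparison B leukocyte 0.264, venous 0.151, and comparison C matrix 0.0905, TGFβ targets 0.16. Calls gained with limma-voom were, comparison A cholesterol 0.0127, and comparison B fatty acid oxidation 0.0188, TCA 0.00674, and comparison C TCA 0.0063. Calls lost in the RPM table were, comparison A leukocyte 0.0958, smooth muscle 0.058, venous 0.693, and comparison B leukocyte 0.149, venous 0.229, and comparison C cholesterol 0.0886, matrix 0.0942, TGFβ targets 0.139. Calls gained in the RPM table were, comparison A cholesterol 0.0229, immediate early 0.0482, and comparison B fatty acid oxidation 0.0414, TCA 0.00712, and comparison C TCA 0.00208. With a library left out, the adjusted p of the lists whose call changed ranged as follows: EMT factors in A 0.0327 to 0.0767, smooth muscle in A 0.0334 to 0.675, smooth muscle in C 0.0329 to 0.184, immediate early in B 0.0481 to 0.226, TCA in C 0.0237 to 0.11, TCA in B 0.0451 to 0.107, venous in A 0.0136 to 0.0599. A stricter filter tests fewer genes, and the cause of the other changes was not tested.

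Log2 fold changes of named genes that turned sign were, with library totals alone, DLST 0.0091 (B), FGFR1 0.11 (B), NRP1 0.092 (C), SMAD2 0.011 (B), SMAD4 0.071 (B), SPARC -0.048 (A), VIM -0.0030 (A), VIM 0.041 (C), VIM 0.044 (B), WWTR1 0.15 (B), and in the RPM table, ACLY 0.013 (B), CDH5 0.0065 (B), DLST 0.030 (B), FGFR1 0.12 (B), LAPTM5 0.0074 (C), NRP1 0.11 (C), SMAD2 0.022 (B), SMAD4 0.094 (B), SPARC -0.051 (A), VIM -0.0057 (A), VIM 0.066 (C), VIM 0.072 (B), WWTR1 0.17 (B). PECAM1 in comparison B turned to -0.089 with TMM factors and -0.12 with DESeq2 factors. Library totals alone moved the median gene by -0.13 (A), 0.26 (B) and 0.13 (C) log2, and the RPM table by -0.13, 0.27 and 0.14. Each sign change under either went in the direction of that shift. With library totals alone only the scaling differed, so these signs depend on it. The RPM values are also scaled to library totals, so the RPM table is not a separate check of the scaling. PECAM1, whose main value is from the RPM table, moved the other way with TMM and DESeq2 factors. Of 567 named gene values, 523 kept direction and call with library totals alone, as did 562 of 567 with DESeq2 size factors, 558 of 564 with the DESeq2 test and 563 of 567 with limma-voom. With a library left out, 4966 of 5022 did.

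With the replicate number as a block, 7214, 9318 and 7962 genes changed in the 3 comparisons and 5316 had opposite changes. Same-numbered libraries deviated together at r = -0.082 to 0.058, and 0 of 9 pairs were over 0.1. No pairing by number was therefore detectable, and the labels leave open whether there was one. The adjusted p of the smooth muscle list in comparison A under the block was 0.0546, and no other list call changed.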

Other observations

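Gene families, grouped by symbol prefix after the data were seen and tested with camera, gave 9 calls over 86 families of 15 or more tested members and the 3 comparisons, none of them between siACSS2 and TGFβ cells. Between siACSS2 and control cells, kinesin genes (KIF) were higher in 17 and lower in 8 of 32 cases (adjusted p = 8.02e-07), and solute carrier genes (SLC) were lower in 108 and higher in 38 of 216 (adjusted p = 0.0112). Transmembrane protein genes (TMEM) were lower in 87 and higher in 16 of 164 (adjusted p = 0.00419), and interleukin and receptor genes (IL) were lower in 19 and higher in 7 of 33 (adjusted p = 0.000965). Genes with the prefix RPL were higher in 68 and lower in 0 of 107 cases (adjusted p = 0.000674). Those with the prefix RPS were higher in 45 and lower in 6 of 71 (adjusted p = 0.029). These prefixes take in ribosomal protein genes and pseudogenes, but the members were not checked for other genes. Tetraspanin genes (TSPAN) were lower in 9 and higher in 2 of 16 (adjusted p = 0.0112). Between TGFβ and control cells, collagen genes (COL) rose in 11 and fell in 5 of 19 cases (adjusted p = 0.00492), and IL genes fell in 21 and rose in 6 of 33 (adjusted p = 0.00302). All 9 calls were lost with an estimated correlation, with adjusted p of 0.264 to 0.989. Control replicate 2 deviated from its mates with gene length, at a Spearman's rho of -0.645.

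Of the tests below, those of loss of TGFβ signalling, the other genes with a shared word, pseudogene share and near-identical copies were written after the result was seen, and the others before. TGFBR1 stood below control in siACSS2 cells (log2 -2.73), although induction medium raised it. The lower level was also present in the RPM table, made on other gene models, at -2.516, which argues against the division of reads between models. Of 141 genes that induction medium raised about as much, 0% lay as far below control as TGFBR1 (5th percentile -1.28, median -0.15). That comparison was made after the depth of the TGFBR1 fall had been seen, and it matches genes on the rise alone. It therefore cannot tell whether loss of TGFβ signalling alone accounts for the fall. Of all 2982 other genes of at least 5 CPM on average that induction medium raised, 3 did lie as far below control, TNC (-3.05), SEMA3G (-2.82) and RND1 (-2.76). Such a fall was therefore rare among raised genes but not limited to TGFBR1. Of all words of 7 bases, 735 occur both in ACSS2 mRNA and in the TGFBR1 3' UTR. The best of these ranked 3 for lower expression in siACSS2 cells against the mean of TGFβ and control cells (z = -6.35, against a 5th percentile of -4.52 for the strongest word in shuffled values), 6 against TGFβ cells (z = -5.29, against -4.43) and 1 against control cells (z = -6.46, against -4.34). By chance, 1 of the top 3 words would be among the 735 in 12.9% of cases. Follow-up values were chosen after these ranks were seen. The word shifted by 1 base to end in A ranked 2 against control cells (z = -6.41), though TGFBR1 holds 0 sites of it. In TGFβ against control cells the best word ranked 13921 (z = 1.24). Adjusted for UTR length and GC content, genes with 0, 1 and 2 or more sites had medians of 0.017, -0.04 and -0.067 against control. These values could go with a small effect of the siRNA on the genes that hold the best word, as a set. They do not single out the siRNA, since words absent from ACSS2 mRNA also passed the shuffled bound. Among these were the words ranked 1 and 2 against the mean of TGFβ and control cells (z = -7.68 and -7.52). The word ranked 3 against control cells (z = -5.09) was absent as well. Of the other 1669 genes that hold the best word, 0% lay as far below control as TGFBR1 (5th percentile -0.98, median -0.12). That comparison, too, was made after the depth of the TGFBR1 fall had been seen. It therefore cannot tell whether the word acts on TGFBR1 as on the other genes that hold it. The longest run of bases shared by the ACSS2 and TGFBR1 mRNAs is 12, so a guide strand that matches ACSS2 throughout has no longer unbroken match to TGFBR1. A direct effect of the siRNA through a match of up to that length, or one with mismatches, which were not searched, may account for the fall and stays open, as the siRNA sequence is not given in the sources used here, and so does loss of ACSS2, as cells with another ACSS2 siRNA were not analysed here. Whatever lowered TGFBR1, much of the reversal of the response to induction medium with ACSS2 siRNA could follow from its loss, which was not tested.

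Principal component 3 set siACSS2 replicate 3 apart from replicates 1 and 2. Its deviation did not follow gene length (rho = 0.041) or GC content (rho = 0.006), which argues against these biases. Nor did it follow the siACSS2 change across genes (r = 0.026), though replicate 3 is itself part of that change, which can pull r upward. ACSS2 stood at 1.32 CPM in replicate 3, against 1.62 and 1.76 CPM in replicates 1 and 2, which argues against a weaker knockdown. Its share of counts on pseudogenes was 2.585%, within the 1.951 to 3.044% of the others but below the 3.03 and 3.04% of siACSS2 replicates 1 and 2. Division of reads between near-identical copies could account for its largest deviations: of 81 genes off by 1 log2 or more, 45.7% were pseudogenes, 17.4 times their share of 2.63% among all genes, while fewer distinct molecules stay open at a variance ratio of 4.51. The labels name no biological difference for 1 library, and none other than a weaker knockdown or treatment response was tested.

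Splits of the 6 libraries of a comparison into 3 and 3 were also tested. In each comparison 1 of 10 splits, the real one, called as many genes, and the highest count in the other 9 was 0. Splits are too few for a share under 0.05. The other splits mix libraries of both groups, which widens the spread within each set, so their low counts say little about chance calls.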
